A study of Mus musculus with 38 samples.

How the data were processed

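Small lung vessels of 76 mice were measured on 38 Agilent arrays with 2 channels each, with 1 animal per channel, Cy3 in channel 1 and Cy5 in channel 2. Groups and replicate numbers were taken from the labels: 8 animals in normoxia, 23 in hypoxia, and 11, 12, 12 and 10 animals after 1, 3, 7 and 14 days of normoxia that followed hypoxia. The vessels were collected by laser microdissection from sections of 10 µm stained for nuclei, per the labels' protocols, so that each dissection can hold neighbouring lung tissue. Each animal counted as 1 replicate.

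The deposited values are log ratios of the 2 channels of an array, 1 value per feature. The authors used limma, per the submitters' processing notes, which give no version. Image analysis, background correction and normalization are not given in the sources used here. The log base is not stated. The deposited values were read as log10 ratios, because they are small: the median SD of an array was 0.114 and the largest value 1.12. This does not settle the base, since limma commonly works on log2 values, which the design fixed before the data were examined had assumed. The tests do not depend on the base apart from the alternative with a minimum of 2-fold, and folds are given for both bases. The direction, Cy5 over Cy3, follows the convention of limma and is not stated. Array medians lay between -0.00306 and 0.00678, so the arrays had been centred, and array SDs between 0.0742 and 0.192. Scanner files, brightness, slide and scan date were not used here, so no filter on dim features and no test of batches was made. The number of arrays limits the precision.

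Of 45220 features, 2 with a missing value were left out. Gene symbols came from the platform annotation, which can be old: 33653 features had 1 symbol, 56 several and 11511 none, and 0 symbols changed when checked against a RefSeq table of assembly GRCm38.p6, used for names only. Features of 1 gene were averaged, for 8343 genes with more than 1 feature, and features without a single symbol were kept as entries of their own. This gave 30653 entries, 19087 of them named genes and 11566 unnamed features, which can include control spots. No coordinates are given because the build of the probes is not stated.

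Log ratios were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 over the 38 arrays, with an intercept for the dye effect and 5 condition terms against hypoxia, so that a swapped array entered with the opposite sign. The fit had 32 residual degrees of freedom and a median residual SD of 0.0821, and 290 entries had a dye effect past the threshold. Tests allowed either direction. The p values of each of 12 contrasts were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Comparisons with normoxia after the return run through hypoxia. Values are given as log ratio ± SE from the fit.

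For hypoxia against normoxia, the genes named were the 12 with the largest log ratio in each direction among those with 1 symbol, past the threshold and with the same sign on all direct arrays after the dye effect was removed. For days against hypoxia up to 6, and for steps between days and days against normoxia up to 4, were named in each direction, and where none passed the 3 with the smallest p. Of each described gene list up to 4 members with the smallest p were named. In all, 39 gene lists were fixed before the data were examined, with 714 members, of which 660 were measured. Lists were tested with camera and a correlation estimated from the data, adjusted over the 39 lists, with a preset correlation of 0.01 and fry as alternatives.

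The return of the hypoxia response was measured by the count of entries called with the opposite sign, medians and the correlation across genes, as fixed before the data were examined. The slope of each day's log ratios on those of hypoxia minus normoxia was added after the data were seen. It was fitted per array over the 30 arrays without a normoxia animal, so that the days and the reference difference shared no array, and tested with 100000 permutations. Alternatives with other settings used 10000 and those with an array left out 1000.

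Alternatives fixed before the data were examined were a fit without the dye term, arrays scaled to 1 spread, arrays centred on their medians, single probes, the probe with the largest SD, a filter on low SD, robust empirical Bayes, array weights, the replicate number as a block, direct arrays alone, a minimum of 2-fold, and each array left out in turn. Scaling used the median absolute value of each array, and the fold minimum was set on the log10 scale. Added after the data were seen were the alveolar marker score as a covariate, a fit without both arrays with day 3 in Cy3 and day 1 in Cy5, and named genes only. The steps were tested on simulated data in which 200 of 30653 entries were changed by known amounts. For hypoxia against normoxia, 35% of 40 entries changed by 0.1 and 92.5% of 40 changed by 0.2 were recovered, with 7 unchanged entries called. For day 7 against hypoxia the shares were 35% and 87.5%, for day 14 against hypoxia 32.5% and 95%, and for day 3 against normoxia, which runs through hypoxia, only 12.5% and 62.5%, with 4, 6 and 4 unchanged entries called. Changes of 0.05 were recovered in 12.5%, 10%, 10% and 0% of entries, in the same order of comparisons. A fall of 0.05 was also planted in the elastic fibre list. Camera missed it in hypoxia against normoxia (adjusted p = 0.66) and day 3 against normoxia (0.742). It passed in day 7 (0.0287) and day 14 (2.15e-05) against hypoxia. Noise was drawn for each entry alone, without correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.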

Results

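Gene expression was measured in small vessels of the mouse lung to follow how the vasculature changes after chronic hypoxia and after the return to normal oxygen. Intrapulmonary vessels of 50 to 100 µm outer diameter were cut out of lung sections by laser microdissection from C57BL/6J mice aged 12 to 18 weeks. The animals had spent 21 days in normoxia (inspired oxygen fraction 0.21, 8 animals) or in hypoxia (0.10, 23 animals), or had been returned to normoxia after hypoxia for 1 day (11 animals), 3 days (12), 7 days (12) or 14 days (10). RNA of these 76 animals was hybridised on 38 Agilent arrays with 2 dyes, with 1 animal in each channel, so that every array gave the ratio between 2 animals. Normoxia was set against hypoxia on 8 arrays, 4 in each dye orientation. Days 1, 3 and 7 were set against hypoxia on 4 arrays each, in both dye orientations. Day 14 was set against hypoxia on 3 arrays that all hold hypoxia in Cy3, and a further 15 arrays joined the days to each other. An array is named by its condition in Cy3, its condition in Cy5 and a replicate number, with H for hypoxia, N for normoxia and N1, N3, N7 and N14 for the days after hypoxia. Values are log ratios whose base is not stated; they were read as log10 from their small size, which does not settle it. The sign rests on the usual convention of Cy5 over Cy3, which makes the directions given here likely and not settled, since a turned sign would reverse all of them. The number of arrays limits the precision of each value, and brightness of the spots was not used here.

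The first question was how vessels of hypoxic mice differed from those of normoxic mice. In hypoxia, Scn7a, a member of the sodium channel family, was higher by a log ratio of 0.270 ± 0.051 (SE, 8 direct arrays), which is 1.86-fold if the base is 10 and 1.21-fold if it is 2. The surfactant protein gene Sftpb rose by 0.215 ± 0.039 and Gpx3, a secreted glutathione peroxidase, by 0.194 ± 0.029. The growth cone gene Gap43 (0.269), the ceramide synthase Cers2 (0.205) and Chil3, a chitinase-like protein of macrophages (0.2004), rose as well. Lower in hypoxia were the small heat shock protein Hspb1 (-0.300 ± 0.051), the chemokine Ccl9 (-0.278 ± 0.047), the hyaluronan receptor Lyve1 (-0.251 ± 0.035) and the matrix glycoprotein Thbs1 (-0.249 ± 0.054). Each of these genes had the same sign on 8 of 8 direct arrays, which the rule for naming them required. Their limma adjusted p values lay between 0.000102 for Lyve1 and 0.0236 for Chil3.

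Of 30653 entries tested, 1102 passed an adjusted p of 0.05 in limma, 413 higher and 689 lower in hypoxia, with a median size of 0.117. Of these, 702 were named genes (294 higher, 408 lower), of which 370 had the same sign on all 8 direct arrays. Larger rises with fewer arrays in agreement, such as that of Dbp, are left out of this ranking. Among these 370, with signs read after removal of the dye effect, large rises were also those of Inka2 (0.215), Grap (0.213), Rnf181 (0.206), Bex1 (0.204), Tnfrsf18 (0.201) and Ddx6 (0.198). The largest falls among them, beside those given above, were those of the phosphatase subunit Ppp2r2c (-0.311), the secreted Wnt modulator Sfrp2 (-0.300), Btbd35f1 (-0.274), the endothelial protein C receptor Procr (-0.274), the macrophage lectin Clec10a (-0.271), Map3k7cl (-0.257), Map3k6 (-0.241) and Plbd1 (-0.236), with adjusted p values up to 0.0414. The count was 659 without array H_N 2, 528 without array N_H 3 and 103 on the 8 direct arrays fitted alone. With the alveolar marker score of each array as a covariate it was 25, and of the 24 named genes given here Hspb1 alone still passed (-0.374, adjusted p = 0.0330). Sizes with the covariate were lower for most of these genes, most of all for Gpx3 (0.0798 ± 0.0344), Ddx6 (0.0584 ± 0.0618) and Sftpb (0.108 ± 0.054), and were not lower for Cers2 (0.242 ± 0.056), Bex1 (0.248), Ppp2r2c (-0.383 ± 0.095), Sfrp2 (-0.362), Hspb1 and Thbs1 (-0.254 ± 0.081). Sftpb is itself a member of the alveolar score, so its drop is partly built in. The SE rose for each of the 24.

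**Figure D1:**
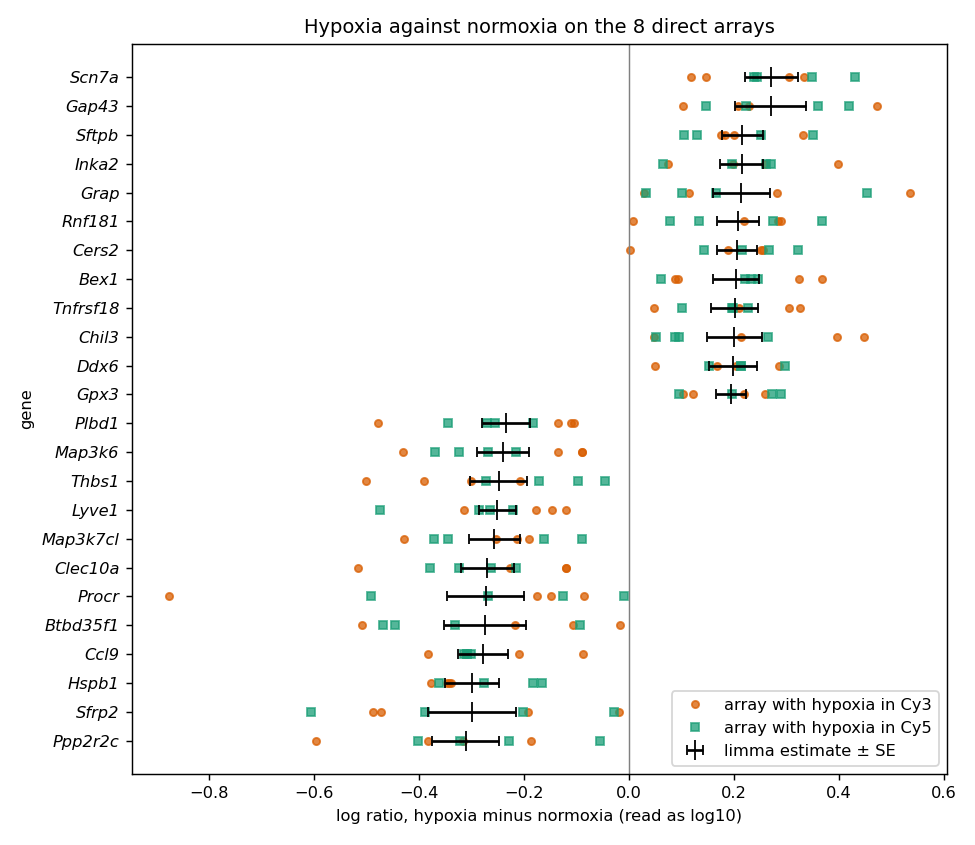
Log ratios of hypoxia minus normoxia (x axis, read as log10) for the 24 named genes (y axis) on the 8 direct arrays, after the fitted dye effect was removed. Circles are arrays with hypoxia in Cy3, squares are arrays with hypoxia in Cy5, and black marks are limma estimates with SE. Every array lies on the side of its gene's estimate, as the rule for naming genes required, from Scn7a at 0.270 to Ppp2r2c at -0.311.

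Markers of lung tissue next to the vessels were among the genes raised in hypoxia. Of 13 measured alveolar type 2 markers, 13 were higher and 5 passed over all genes (10 adjusted over the list alone), with a list median of 0.0757 and an adjusted p of 0.00815 in camera with an estimated correlation. They included Sftpb, the aspartic protease Napsa (0.118), Cxcl15 (0.117) and the lipid transporter Abca3 (0.0967). Of 13 alveolar type 1 markers, 6 rose (9 higher and 1 lower adjusted over the list alone), with a median of 0.105 and an adjusted p of 0.0157. Examples were Clic5 (0.173), Igfbp2 (0.144), the water channel Aqp5 (0.111) and Gprc5a (0.0756). The mean of both lists was higher in hypoxia on 8 of 8 direct arrays, by 0.0914.

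Inflammatory cytokines and chemokines fell together in hypoxia. The list median was -0.0463 over 25 members, 23 of which were lower, and 4 passed over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0395). The 4 were Ccl9, the chemokine Ccl17 (-0.213) and the endothelial adhesion molecules Vcam1 (-0.132) and Sele (-0.107). The list no longer passed without H_N 2 (adjusted p = 0.0871), H_N 4 (0.0569) or N_H 3 (0.127), nor per probe (0.164) or with the alveolar score as a covariate (median -0.0126, adjusted p = 0.486). These 3 lists of 39 passed with an estimated correlation, against 11 with the preset correlation of camera and 13 with fry, which tests only whether the members of a list move 1 way on balance.

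Some lists held several genes that passed while the list itself did not, and 4 of them were chosen for description after their values were seen. Among 22 smooth muscle contractile genes, 5 fell (9 lower and 1 higher adjusted over the list alone), including calponin Cnn1 (-0.190 ± 0.035), Actg2 (-0.172 ± 0.034), smooth muscle actin Acta2 (-0.116 ± 0.024) and tropomyosin Tpm2 (-0.111 ± 0.026). The list median was -0.0436, with adjusted p = 0.177 with an estimated correlation and 7.33e-05 with the preset one. Among 15 heat shock genes, 4 fell (9 adjusted over the list alone), namely Hspb1, Hsph1 (-0.235), Hsp90aa1 (-0.231) and Hspe1 (-0.0969), with a list median of -0.0893 and adjusted p = 0.0996 with an estimated correlation. Among 17 circadian clock genes, the clock output genes Dbp (0.347) and Tef (0.194) and the repressor Nr1d1 (0.1498) rose, and Per3 stood at 0.205 without passing (adjusted p = 0.0590). Nr1d1 passed in 21 of the 38 fits without 1 array and in 7 of 13 other settings. That list had 5 higher and 1 lower adjusted over the list alone, a median of 0.0627 and adjusted p = 0.0996 with an estimated correlation. Among 19 antioxidant genes, the glutathione peroxidases Gpx3 and Gpx2 (0.0982) rose (3 adjusted over the list alone) and Srxn1 stood at -0.0720 without passing, with a median of 0.0441 and the same adjusted p of 0.0996 with an estimated correlation. With the alveolar score as a covariate no list passed in this comparison. Of the genes named in this paragraph, Hspb1 alone then passed. Alveolar markers were higher on the same arrays, so tissue composition and a change in the vessel wall cannot be told apart here.

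**Figure D2:**
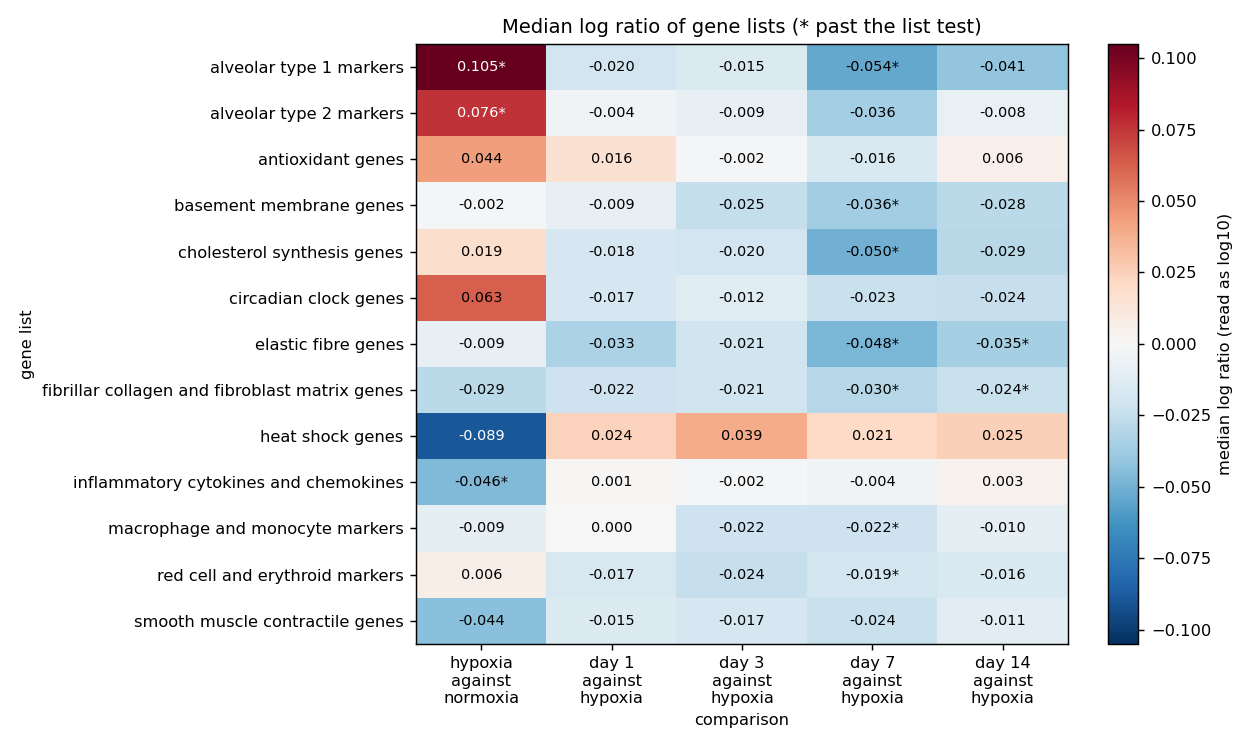
Median log ratio (colour and printed value, read as log10) of 13 gene lists (y axis) in hypoxia against normoxia and in each day against hypoxia (x axis). Stars mark lists past the camera test with an estimated correlation; the alveolar lists were higher in hypoxia (0.105 and 0.0757), and 7 lists were lower on day 7, among them elastic fibre genes at -0.0477.

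The next question was what changed once the mice breathed normal oxygen again. After 1 day, no entry passed in limma, and 1217 had an unadjusted p under 0.05 where 1533 are expected by chance. The smallest p values among higher genes were those of Srrm2 (0.0935), Zdhhc6 (0.151) and Rora (0.0860), and among lower genes those of Vstm4 (-0.154), Olfr437 (-0.0737) and Serf2 (-0.0759), each with an adjusted p of 1.00. No list passed in camera with an estimated correlation, with 3 at an unadjusted p under 0.05, 1 past with the preset correlation and 0 with fry.

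After 3 days, Bloc1s4, a subunit of a complex for lysosome-related organelles, was lower than in hypoxia by a log ratio of -0.178 ± 0.030 (adjusted p = 0.0178), and Vwa8 was higher by 0.0871 ± 0.0160 (adjusted p = 0.0401), each with the same sign on 4 of 4 direct arrays. With 2 features that have no single gene symbol, they made up the 4 entries that passed. At an unadjusted p under 0.05 there were 2827. The count was 0 without array H_N3 1, 0 with array weights, 0 on the direct arrays alone and 44 with the alveolar score as a covariate, and Vwa8 passed in 19 of the 38 fits that left out 1 array. No list passed in camera with an estimated correlation, with 2 at an unadjusted p under 0.05, 6 past with the preset correlation and 0 with fry.

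After 7 days, the haemoglobin genes stood out. Hba-a2 was lower than in hypoxia by a log ratio of -0.431 ± 0.071 (adjusted p = 0.0161), 2.70-fold if the base is 10 and 1.35-fold if it is 2, Hbb-bt by -0.412 ± 0.072 and Hba-a1 by -0.366 ± 0.065 (adjusted p = 0.0164 for each). The 2 alpha globin genes are near identical, so their probes may not be separate evidence, although both are counted here, in the red cell list and in the haemoglobin mean. Sparc, a matrix protein of the vessel wall, fell by 0.127 ± 0.023 (adjusted p = 0.0164), and the calcium pump gene Atp2c2 rose by 0.149 ± 0.025 (adjusted p = 0.0161). Each had the same sign on 4 of 4 direct arrays, and these 5 were all that passed (1985 at an unadjusted p under 0.05). Sparc passed in 6 of 13 other settings. On day 3 against hypoxia the haemoglobin genes already stood at -0.281 (Hba-a2), -0.179 (Hbb-bt) and -0.234 (Hba-a1) without passing. None of them passed from day 3 to day 7. In hypoxia against normoxia they differed by only 0.00554 to 0.0266. The count was 0 without N7_H 2, 0 without H_N7 1, 1 without H_N7 2 and 3 without N7_H 1. With the alveolar score as a covariate none of the 5 passed (adjusted p = 0.437 for each) and 1 other entry did, while the log ratios were -0.349 ± 0.080 for Hba-a2, -0.334 ± 0.082 for Hbb-bt, -0.286 ± 0.073 for Hba-a1, -0.101 ± 0.026 for Sparc and 0.127 ± 0.029 for Atp2c2.

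Matrix genes of the vessel wall were lower on day 7 as groups. Of 14 elastic fibre genes, 13 were lower, with a median of -0.0477 (camera adjusted p = 0.000369). None passed over all genes and 3 did adjusted over the list alone: the microfibril proteins Mfap5 (-0.170) and Mfap4 (-0.121) and Ltbp2, a latent TGF-beta binding protein (-0.149). Fibulin Fbln2 had -0.0772 and did not pass. The list passed in each of the 38 fits without 1 array and in 11 of 11 other settings. Basement membrane genes had a median of -0.0364 over 16 members (adjusted p = 0.0125; 0 over all genes, 2 adjusted over the list alone), with Col4a2 at -0.104 and Col4a3 at -0.0770. Fibrillar collagen and fibroblast matrix genes had a median of -0.0296 over 21 members (adjusted p = 0.0186; 1 over all genes, 4 adjusted over the list alone). Sparc was the 1, and Col3a1 (-0.0868), Fn1 (-0.118) and Col1a2 (-0.0892) were past in the list alone. Without H_N7 1 the fibrillar collagen list did not pass (adjusted p = 0.0937). With the filter on low SD neither that list (adjusted p = 0.0599) nor the basement membrane list (0.0675) passed, and the latter did not per probe (0.346). On day 3 against hypoxia Mfap4 (-0.127 ± 0.028) and Sparc (-0.105 ± 0.022) were already lower without passing. No list passed from day 3 to day 7, so the start of the fall is not dated to day 7.

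The alveolar markers of both types together had a mean of -0.0502 ± 0.0140 on day 7 (permutation p = 0.0168), beside these matrix groups. A further 4 lists were lower on that day. Cholesterol synthesis genes had a median of -0.0501 over 17 members (adjusted p = 0.00393; 0 over all genes, 2 adjusted over the list alone), with Idi1 at -0.123 and Msmo1 at -0.0908. Red cell and erythroid markers had a median of -0.0190 and a mean of -0.118 over 13 members (adjusted p = 0.00180; 3 over all genes, 4 adjusted over the list alone), a gap set by the haemoglobin genes. Alveolar type 1 markers had a median of -0.0539 with 13 of 13 members lower (adjusted p = 0.0205; 0 over all genes, 3 adjusted over the list alone), with Pdpn at -0.164, Spock2 at -0.108 and Igfbp2 at -0.0724. Macrophage and monocyte markers had a median of -0.0220 over 19 members (adjusted p = 0.0387; 0 over all genes and 0 adjusted over the list alone), with Adgre1 at -0.0869, Retnla at -0.104 and Trem2 at -0.0657, while Arg1 was higher at 0.0559. The macrophage list did not pass without any 1 of 10 arrays (adjusted p up to 0.132, without H_N7 2) or with the filter on low SD (0.139). The alveolar type 1 list did not pass without N7_H 2 (0.0692) or H_N7 2 (0.0558), with that filter (0.0599) or per probe (0.156). With the alveolar score as a covariate, the elastic fibre and red cell lists still passed (adjusted p = 0.0279 for each) and the other 5 lists did not. Of these 5, fibrillar collagen genes then had a median of -0.0357 (adjusted p = 0.187), macrophage markers -0.0313 (0.583) and cholesterol synthesis genes -0.0350 (0.209), while basement membrane genes stood at -0.0157 (0.583) and alveolar type 1 markers, which enter the score, at -0.00293 (0.929). With the preset correlation 13 lists passed, and 7 with fry.

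After 14 days, no entry passed in limma (1234 at an unadjusted p under 0.05). Elastic fibre genes stood at a median of -0.0345 against hypoxia (camera adjusted p = 0.00383; 0 over all genes, 1 adjusted over the list alone) and fibrillar collagen and fibroblast matrix genes at -0.0236 (adjusted p = 0.0224; 0 and 1). Mfap4 (-0.126) was the elastic fibre gene past in its list alone, and Sparc (-0.113) the gene past in the collagen list. Of the collagen list, Col1a1 (-0.116) and Fn1 (-0.129) were lower and Dcn was higher (0.0953), none of them past in the list alone. The smallest p values over all genes were those of Sparc, the phagocytosis bridge Mfge8 (-0.0877) and the integrin Itga3 (-0.0785) among lower genes, and of Mzt1 (0.111), Plekhs1 (0.0956) and 2900041M22Rik (0.0535) among higher ones. Without array H_N14 3, Sparc alone passed (-0.143, adjusted p = 0.00887). Both lists lost their call with the alveolar score as a covariate, at medians of -0.0334 (adjusted p = 0.0632) and -0.0272 (0.103) that were close to those without it. The collagen list also lost it without N1_N14 2 (0.0562) or N7_N14 1 (0.0520), and 7 lists passed with the preset correlation and 2 with fry. Whether day 7 and day 14 differed in these lists was tested in the step between them, where no list passed.

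**Figure D3:**
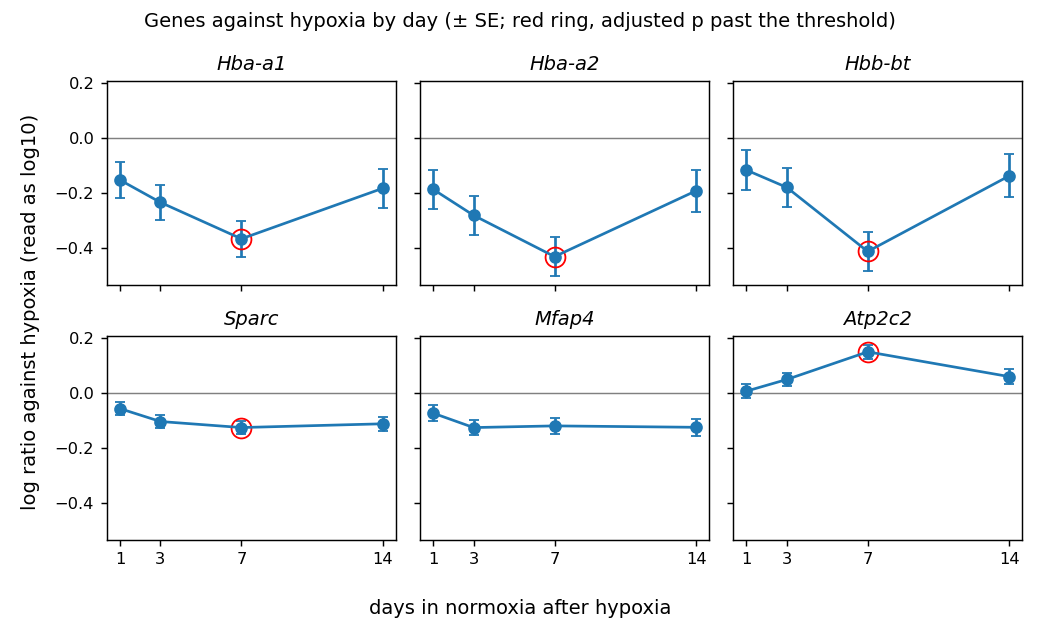
Log ratio against hypoxia (y axis, read as log10, with SE) by days in normoxia after hypoxia (x axis) for Hba-a1, Hba-a2, Hbb-bt, Sparc, Mfap4 and Atp2c2, each panel a gene. Red rings mark the values past the adjusted p threshold, all on day 7; Hba-a2 stood at -0.186, -0.281, -0.431 and -0.191 on days 1, 3, 7 and 14.

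Whether the hypoxia response was undone in normoxia was measured over the 1102 entries that differed between hypoxia and normoxia. None of them passed with the opposite sign against hypoxia in limma on any day. At an unadjusted p under 0.05, 37 had the opposite sign and 15 the same sign on day 1, 77 and 52 on day 3, 111 and 8 on day 7, and 61 and 9 on day 14. The 413 entries raised in hypoxia (median 0.133 against normoxia) had medians against hypoxia of -0.00915, -0.00691, -0.0271 and -0.0205 on days 1, 3, 7 and 14. The 689 lowered ones (median -0.110) had medians of -0.00468, -0.00206, 0.0147 and -0.00102. The share that lay on the side of normoxia was 47.8% on day 1, 49.9% on day 3, 75.3% on day 7 and 58.4% on day 14. Across these entries, which are not independent replicates, the log ratios of the day correlated with those of hypoxia at r = -0.134, -0.0951, -0.564 and -0.392.

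A slope of the day's log ratios on those of hypoxia, in which -1 is a full return, was added after the data were seen so that arrays could serve as replicates. It was -0.0257 ± 0.0634 on day 1 (permutation p = 0.757), -0.0266 ± 0.0616 on day 3 (p = 0.732), -0.163 ± 0.062 on day 7 (p = 0.0826) and -0.0985 ± 0.0681 on day 14 (p = 0.235), over the 30 arrays that hold no normoxia animal. With adjustment over the 4 days the smallest p was 0.330, on day 7. In this fit no day's slope passed the permutation test. That test shuffled the labels of hypoxia and the day over the channels and is not a test against the SE. With the alveolar score as a covariate the slope ran over the 25 entries called with that covariate, of which 16 were also called without it. It was -0.188 on day 3 (permutation p = 0.0173) and -0.185 on day 7 (p = 0.0148), neither adjusted over the days. As the set of entries differs, these values do not show how far the slopes given above depend on the alveolar score. On direct arrays alone the slopes were -0.177, 0.157, -0.328 and 0.0260 on days 1, 3, 7 and 14. The 3 direct arrays of day 14 all hold hypoxia in Cy3, so that the last value cannot be separated from a dye effect. Sizes of genes chosen in hypoxia against normoxia are inflated by the choice: genes chosen on replicates 1 and 2 had a slope of 0.492 on the other arrays of that comparison, and genes chosen on replicates 3 and 4 a slope of 0.468. With genes chosen on replicates 1 and 2 and sized on the others, the day 7 slope was -0.225 (permutation p = 0.0383), and -0.207 (p = 0.0419) the other way round, neither adjusted over the days.

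**Figure D4:**
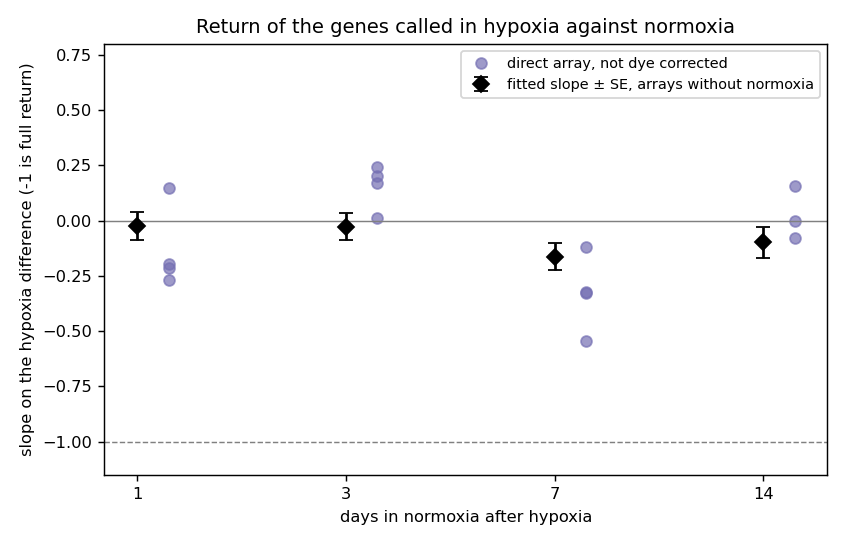
Slope of each day's log ratios on those of hypoxia minus normoxia (y axis, no unit; -1 is a full return, dashed) by days in normoxia after hypoxia (x axis, evenly spaced). Diamonds are fitted slopes with SE over 30 arrays, from -0.0257 on day 1 to -0.163 on day 7, and circles are single direct arrays without dye correction.

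Changes from each day to the next were looked at directly. From day 1 to day 3 no entry passed in limma (1418 at an unadjusted p under 0.05). The smallest p values were those of the channel gene Asic5 (0.171), Zfp334 (0.143) and Bbs7 (0.146) among higher genes and of the macrophage receptor Adgre4 (-0.0906), Elmo2 (-0.142) and Arfgef3 (-0.0776) among lower ones, with adjusted p values from 0.359 to 0.422. From day 3 to day 7, 1700088E04Rik fell by 0.158 ± 0.025 (adjusted p = 0.0123, 4 of 4 direct arrays), together with 2 features without a single gene symbol (3135 at an unadjusted p under 0.05), and without N3_N7 2 or N7_N3 1 the count was 0. From day 7 to day 14 no entry passed (1123 at an unadjusted p under 0.05). Gm6639 (0.0682), Cox7b2 (0.0588) and Endou (0.173) had the smallest p values among higher genes and Ppt2 (-0.129), Tmbim1 (-0.0896) and the Wnt co-receptor Lrp5 (-0.0640) among lower ones, each with an adjusted p of 1.00. No list passed in camera with an estimated correlation in any of these 3 steps, with 1, 2 and 2 lists at an unadjusted p under 0.05, 0, 0 and 2 past with the preset correlation and 0 in each with fry.

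The last question was what still differed from normoxia after the return. No array held a returned animal beside a normoxic one, so these values run through hypoxia and contain the hypoxia against normoxia difference. After 1 day, 34 entries passed (11 higher, 23 lower; 3484 at an unadjusted p under 0.05). The radical SAM family gene Rsad1 (0.430 ± 0.094), Zfp799 (0.349), Inka2 (0.265) and Ppp1r9a (0.180) were higher than in normoxia. Lower were Wfdc17 (-0.315 ± 0.060), Gfpt2 (-0.295), which feeds glucose into the hexosamine pathway, the macrophage scavenger receptor Cd163 (-0.293) and 4930433I11Rik (-0.287). Without both arrays that hold day 3 in Cy3 and day 1 in Cy5, an alternative chosen after the data were seen, no entry passed. Those 2 arrays correlated with each other at r = 0.546, where no other pair with the same 2 conditions in the same dyes exceeded 0.282 and pairs with swapped dyes reached -0.430. The cause was not tested, so whether they count as 2 independent replicates is open. The count ran from 1 (without N3_N1 2) to 98 (without H_N7 1), and of the 38 fits without 1 array Rsad1 passed in 9, Inka2 in 12, Cd163 in 13, Ppp1r9a in 19 and Zfp799 in 21.

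After 3 days, 240 entries passed (92 higher, 148 lower; 4375 at an unadjusted p under 0.05). Rsad1 (0.444 ± 0.092), the SNARE protein gene Stx11 (0.398), 4632404H12Rik (0.323) and the matrix protein gene Tnn (0.301) were higher, and Map3k7cl (-0.292), Hspb1 (-0.286), Wfdc17 (-0.275) and Ccl9 (-0.273) were lower than in normoxia. The count was 75 with all arrays scaled to 1 spread, 6 with the alveolar score as a covariate and 56 without H_N3 2, and of the 38 fits without 1 array 4632404H12Rik passed in 12, Tnn and Hspb1 in 13 each, Ccl9 in 29, Map3k7cl in 30, Stx11 and Wfdc17 in 36 each and Rsad1 in 37. On days 1 and 3 no list passed in camera with an estimated correlation, with 8 and 8 at an unadjusted p under 0.05, 10 and 6 past with the preset correlation and 5 and 6 with fry.

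After 7 days, 7 genes were lower than in normoxia and none higher (2606 at an unadjusted p under 0.05). The largest were Wfdc17 (-0.351 ± 0.059), Ccl9 (-0.349 ± 0.066), the TWEAK receptor Tnfrsf12a (-0.229) and the macrophage lectin Mgl2 (-0.205). The count ran from 3 (without N_H 3) to 12 (without H_N7 1) and was 19 per probe (1 higher, 18 lower) and 4 with the alveolar score as a covariate. Ccl9 passed in 28 and Tnfrsf12a in 35 of the 38 fits without 1 array, and Ccl9 in 7 of 12 other settings. Fibrillar collagen and fibroblast matrix genes (median -0.0691; 1 over all genes, 2 adjusted over the list alone), elastic fibre genes (-0.0615; 0 and 4) and inflammatory cytokines and chemokines (-0.0531; 1 and 1) fell as lists, each at a camera adjusted p of 0.0378. No list passed without 6 of the 38 arrays, left out 1 at a time. After 14 days, 8 entries passed (1 higher, 7 lower; 2694 at an unadjusted p under 0.05), with Mgl2 (-0.207 ± 0.037), the matrix glycoprotein Tinagl1 (-0.190), Ifna9 (-0.182) and the collagen gene Col2a1 (-0.152) lower. The count was 0 without H_N 2, 41 without N_H 4, 0 with the alveolar score as a covariate and 65 with array weights, and Ifna9 passed in 15 and Tinagl1 in 19 of the 38 fits without 1 array. The fibrillar collagen list had a median of -0.107 (camera adjusted p = 0.0475; 0 over all genes, 4 adjusted over the list alone) and lost its call without any 1 of 25 arrays. With the preset correlation 11 and 9 lists passed on days 7 and 14, and 5 and 5 with fry.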

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

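Tests of single arrays that lie far from the others of their comparison followed a fixed rule. They were not applied to day 14 against hypoxia, with 3 direct arrays, or to the days against normoxia, which have no direct array. Of 112 values tested, 6 (5.36%) had such an array, and chance gives about 1 in 20. In hypoxia against normoxia, Hspe1 stood at -0.0171 on N_H replicate 2, with -0.139 to -0.0812 on the other 7 arrays. Srxn1 stood at -0.373 on N_H replicate 3, with -0.108 to 0.0451 on the others. In day 1 against hypoxia, Olfr437 stood at -0.254 on N1_H replicate 3, with -0.0654 to -0.0457 on the others. In day 7 against hypoxia, the cholesterol synthesis genes Pmvk (0.0923, others -0.0954 to -0.0706) and Srebf2 (0.0483, others -0.113 to -0.0901) stood apart on the same array, H_N7 replicate 2. From day 1 to day 3, Elmo2 stood at 0.0799 on N1_N3 replicate 1, with -0.278 to -0.219 on the others.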

How the results depend on the processing

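The covariate, the fit without both arrays with day 3 in Cy3 and day 1 in Cy5, the fit on named genes only and the slopes were tests chosen after the data were seen. The cause of the differences below was not tested, except that named genes only, direct arrays and a size minimum use fewer entries or arrays by construction. Brightness was not used here, so what signal over background limits is open. The counts with at least 2-fold below hold only if the base is 10. With base 2 no called entry would reach 2-fold, as the largest called log ratio was 0.483, in day 14 against normoxia.

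Hypoxia against normoxia gave 1102 called entries, and 960 when scaled (926 shared), 1074 when centred (1040 shared) and 974 without the dye term (973 shared). It gave 25 with the alveolar covariate, 710 with named genes only, 6 with at least 2-fold and 103 on direct arrays. Leaving out 1 array gave 528 (N_H 3) to 1316 (N3_N7 2), with 659 without H_N 2. For day 3 against hypoxia (4), the count was 2 when scaled (0 higher, 2 lower, against 2 and 2), 0 with array weights, 44 with the covariate, 1 without both arrays of day 3 and day 1, 2 with named genes only, 0 with 2-fold and 0 on direct arrays, and 0 (H_N3 1) to 8 (H_N14 3) without 1 array, with 18 arrays that moved it. For day 7 against hypoxia (5), it was 1 with array weights, 1 with the covariate, 3 with 2-fold and 0 on direct arrays, and 0 to 7 without 1 array (0 without N7_H 2 or H_N7 1, 1 without H_N7 2, 3 without N7_H 1). Day 14 against hypoxia gave 0 to 1 (1 without H_N14 3). From day 1 to day 3 (0), 1 passed per probe and 10 with array weights. From day 3 to day 7 (3), the count was 0 when scaled, 10 per probe, 6 with the probe of largest SD, 0 with array weights, 0 with the covariate, 1 with named genes only, 0 with 2-fold and 0 on direct arrays, and 0 (N3_N7 2, N7_N3 1) to 6 (H_N3 1) without 1 array, with 7 arrays that moved it. Leaving out 1 array gave 0 in day 1 against hypoxia, in day 3 against day 1 and in day 14 against day 7.

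For day 1 against normoxia (34), the count was 18 without the dye term, 19 with the low-SD filter, 152 with array weights, 1 with the covariate, 0 without both arrays of day 3 and day 1, 21 with named genes only and 5 with 2-fold, and 1 (N3_N1 2) to 98 (H_N7 1) without 1 array, with 19 arrays that moved it. For day 3 against normoxia (240), it was 75 when scaled, 127 with the low-SD filter, 100 with array weights, 6 with the covariate, 135 with named genes only and 13 with 2-fold. Without 1 array it was 56 (H_N3 2) to 335 (H_N7 1), with 57 without N3_H 1, 85 without H_N3 1, 91 without N_H 3, 104 without H_N 2, 121 without N3_H 2, 138 without H_N 3 and 157 without N_H 2. For day 7 against normoxia (7), it was 19 per probe, 2 with the low-SD filter, 4 with the covariate and 2 with 2-fold, and 3 (N_H 3) to 12 (H_N7 1) without 1 array, with 4 without N_H 2, 4 without H_N 2 and 11 without H_N7 2. For day 14 against normoxia (8; 1 higher, 7 lower), it was 15 without the dye term, 15 when scaled (3 higher, 12 lower), 13 when centred (3 higher, 10 lower), 24 per probe, 3 with the probe of largest SD, 1 with the low-SD filter, 3 with robust empirical Bayes, 65 with array weights, 0 with the covariate, 3 without both arrays of day 3 and day 1, 4 with named genes only and 1 with 2-fold, and 0 (H_N 2) to 41 (N_H 4) without 1 array, with 30 arrays that moved it.

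The 248 array pairs of different groups with the same replicate number had a median residual correlation of -0.0160 (-0.378 to 0.405), with 11.29% over 0.1. The 426 pairs with other numbers had a median of -0.0244. A shared factor can give either sign when the channels differ, so these medians do not settle whether the numbers pair the arrays. With the replicate number as a block, 1091 entries passed in hypoxia against normoxia (1026 shared), 2 in day 3 against hypoxia, 4 in day 14 against normoxia and 0 lists in day 14 against normoxia. The block moved no other count of entries or lists by over 1.5 times. Of 155 single genes and lists it ended 9 calls without turning a sign: Vwa8 on day 3 against hypoxia (adjusted p = 0.0796), macrophage markers on day 7 against hypoxia (0.0518), Inka2 (0.0545), Rsad1 (0.0677) and Zfp799 (0.0655) on day 1, Hspb1 on day 3 (0.0506), Ccl9 on day 7 (0.0555), and Ifna9 (0.0652) and the fibrillar collagen list (0.0629) on day 14 against normoxia.

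The count of entries called with the opposite sign was 0 in each of the 12 other settings and 0 to 3 without 1 array (3 without H_N14 3). The slope of return on day 1 lay between -0.0583 (N1_H 3) and 0.0159 (H_N1 1, a turned sign) without 1 array, on day 3 between -0.0671 and -0.00463, on day 7 between -0.184 and -0.103, and on day 14 between -0.142 and -0.0628. With the covariate it was -0.188 on day 3 (permutation p = 0.0173) and -0.185 on day 7 (p = 0.0148). The covariate fit and the fits that left out arrays each used the entries they called in hypoxia against normoxia, 25 with the covariate. The day 3 slope turned to 0.00662 without both arrays of day 3 and day 1 and to 0.157 on direct arrays, and the day 14 slope to 0.0260 on its 3 direct arrays, which share 1 dye orientation and cannot be separated from a dye effect. On direct arrays the slope was -0.177 on day 1 and -0.328 on day 7. Genes chosen on replicates 1 and 2 gave -0.225 on day 7 and those on replicates 3 and 4 -0.207.

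Lists past in hypoxia against normoxia (3) were 0 with the covariate, 11 with the preset correlation and 13 with fry, and 2 to 4 without 1 array. With the preset correlation, 1, 6, 13 and 7 lists passed on days 1, 3, 7 and 14 against hypoxia, 2 from day 7 to day 14, and 10, 6, 11 and 9 on the days against normoxia. With fry, 5, 6, 5 and 5 passed on the days against normoxia. Day 7 against hypoxia (7) gave 3 with the low-SD filter (elastic fibre, red cell and cholesterol synthesis lists) and 2 with the covariate (elastic fibre and red cell lists), and 5 to 8 without 1 array. Day 14 against hypoxia (2) gave 0 with the covariate, and 1 (N1_N14 2, N7_N14 1) to 4 (N14_N7 2) without 1 array. Day 1 against hypoxia gave 0 to 1 (1 without N1_H 3), and day 1 against normoxia 1 with array weights and 0 to 1 without 1 array. Day 3 against normoxia gave 1 with the low-SD filter and 2 with array weights. Day 7 against normoxia (3) gave 0 per probe, 0 without both arrays of day 3 and day 1, and 0 to 4 without 1 array. Day 14 against normoxia (1) gave 0 centred, per probe, with the low-SD filter and without both arrays of day 3 and day 1, and 2 with array weights and 2 with the covariate, and 0 to 1 without 1 array. Among single values, Fbln2 on day 7 turned to 0.0181 on direct arrays, and the alveolar type 2 (-0.000466) and type 1 (-0.0179) medians in hypoxia turned with the covariate, which is built from them. Named calls that passed in at most 9 other settings were, in hypoxia, Nr1d1 (7 of 13), Abca3 (8 of 12), Acta2 and Gprc5a (9 of 12 each), and Vcam1 and Sele (9 of 13 each). Against hypoxia they were Vwa8 on day 3 (5 of 12) and Sparc on day 7 (6 of 13), and from day 3 to day 7 1700088E04Rik (9 of 13). Against normoxia they were Inka2 (4 of 12), Rsad1 (5), Cd163 and Ppp1r9a (7 each) and Zfp799 (8) on day 1, and Hspb1 (4 of 12), Tnn and 4632404H12Rik (5 each), Ccl9 (8) and Map3k7cl (9) on day 3. They were also Ccl9 (7 of 12) and Tnfrsf12a (9) on day 7, and Ifna9 and Tinagl1 (6 of 12 each) and Col2a1 (9 of 11) on day 14.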

Other observations

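The tests of elastic fibre and haemoglobin genes were written after those values were seen, the alveolar tests after the alveolar difference was seen but before their own values, and the gene groups described first were picked after their values were seen. In hypoxia against normoxia, 3 of 21 matrix protease genes fell: tissue plasminogen activator Plat (-0.189 ± 0.033, limma adjusted p = 0.00119), Timp4 (-0.132) and Mmp3 (-0.139). Their list did not pass in camera with an estimated correlation (median -0.0402, adjusted p = 0.109). Of 22 endothelial genes, Emcn (0.201), Robo4 (0.171) and the VEGF receptor Kdr (0.130) rose and Vwf, which carries von Willebrand factor, fell by 0.113 among 2 that fell (list median 0.0126, adjusted p = 0.709). Of 25 BMP and TGF-beta pathway genes, Tgfb3 (-0.131), Tgfbi (-0.150) and Smad1 (-0.110) fell and Smad5 (0.0954) rose (list median -0.00115, adjusted p = 0.998).

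Of 19 macrophage and monocyte markers, Chil3, the lysozyme gene Lyz2 (0.105) and Trem2 (0.119) rose and Ly6c2 (-0.139) fell in hypoxia. The list median was -0.00918, its mean 0.0101 and its test upward (adjusted p = 0.616). Of 27 hypoxia-inducible and glycolysis genes, Vegfa (0.125, adjusted p = 0.0415), which the alveolar type 1 list also holds, was the 1 that rose, and Pfkfb3 stood at 0.156 without passing (adjusted p = 0.0513). That list had a median of -0.00696 and a mean of 0.00320, with camera upward and fry downward (adjusted p = 0.819 in camera). Of 25 cell cycle genes none passed in limma (list median -0.0237, adjusted p = 0.183 in camera). Lyve1 was the 1 gene called among 9 lymphatic markers, whose median was 0.0796.

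Other splits of the same arrays, 100 per comparison with the real one included, were used to ask whether chance could give as many called entries. Few splits gave as many for hypoxia against normoxia (1 of 100 for a count of 1102, highest other 144) and day 3 against hypoxia (1 of 100 for 4, highest other 1). The same held for day 7 against hypoxia (3 of 100 for 5, highest other 8). For days 1, 3, 7 and 14 against normoxia it was 1 of 100 each (counts of 34, 240, 7 and 8, highest others 1, 2, 3 and 2). More splits did from day 3 to day 7 (11 of 100 for 3, highest other 23). With 100 splits and no adjustment over the 12 contrasts, a rare count argues against chance but does not exclude it. The counts against normoxia also contain the hypoxia against normoxia difference. Where the count was 0, as for days 1 and 14 against hypoxia (highest others 1 and 1) and from day 1 to day 3 and day 7 to day 14 (2 and 2), 100 of 100 splits gave as many. Any split gives at least 0, so that share carries no information.

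Alveolar markers were higher in hypoxia on 8 of 8 direct arrays, by 0.0914, and more alveolar tissue in those dissections may be the reason. Across 1091 called entries outside the alveolar lists, the loading on the alveolar score among the 30 arrays without normoxia correlated with hypoxia minus normoxia at r = 0.588. Of 128 assignments of signs to the 8 arrays, the real one included, 4 others gave as much, up to 0.612. The criterion asked for a value above all others, so the test does not decide. With the score as a covariate, 1.47% of these entries (16) stayed past, which met the criterion written beforehand for alveolar tissue as the whole cause. That criterion was judged inadequate after the result was seen, because the median size went only from 0.117 to 0.0879 while the median SE rose from 0.0280 to 0.0406, and dye and condition take 61.8% of the variance of the score. Composition and a response of alveolar cells to hypoxia therefore cannot be told apart here, and 1085 of the 1091 entries kept their sign.

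Elastic fibre genes were lower on day 7, with a mean of -0.0587 ± 0.0105 against hypoxia (permutation p = 0.00114). Less vessel wall in those dissections would lower smooth muscle genes as much, if the loss lowered both groups alike. Smooth muscle genes had a mean of -0.0146 ± 0.0156. The difference of -0.0441 ± 0.0156 (permutation p = 0.0329) met the criterion set against such an even loss as the whole cause. It does not decide, because the elastic fibre list was singled out by its low values on these same arrays. An uneven loss of wall was not tested. Alveolar markers were lower too (-0.0502 ± 0.0140), so a shift in the surrounding tissue stays open. A fall of matrix genes during the return to normoxia is a hypothesis that these data may fit. The elastic fibre list still passed with the alveolar covariate (adjusted p = 0.0279, and 1.96e-06 to 0.0279 over its 11 other settings). Such a fall is not shown to be a return to the normoxic level. On day 7 the medians were also lower than in normoxia, at -0.0615 for elastic fibre and -0.0691 for fibrillar collagen genes (camera adjusted p = 0.0378 for each). These comparisons with normoxia run through hypoxia and did not pass per probe (adjusted p = 0.147 and 0.341).

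The 3 haemoglobin genes were lower on day 7, with a mean of -0.405 ± 0.075 (permutation p = 0.00186), and less blood left in the vessels is a candidate explanation. The 24 platelet and neutrophil genes, which blood also carries, had a mean of -0.00515 (95% interval -0.0403 to 0.0300, permutation p = 0.805), which met the criterion set against this explanation. The criterion was judged inadequate after the result was seen, because the members of the platelet list hardly moved together (mean correlation 0.0624, against 0.138 for neutrophil and 0.221 for smooth muscle genes), so such genes may lie too near the background to show a loss of blood. A fall in red cell number or haemoglobin transcripts after hypoxia ends was not tested, and the other 10 red cell markers had a mean of -0.0327 ± 0.0104. Less blood and fewer haemoglobin transcripts per vessel cannot be told apart with these arrays.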
